A study of Mus musculus with 2 samples.

How the data were processed

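Total RNA from uterine tissue between implantation sites was hybridised as biotin-labelled cRNA, made from 2 microg of RNA, per the labels' protocols. Each of the groups, control and Cbs null, was represented by 1 array, grouped by the genotype given in the labels. The deposited value table holds 1 intensity per probe set and array on a linear scale. GCOS version 1.4 is named in the submitters' processing notes. The summarisation method, the scaling target and any detection calls are not given in the sources used here. The 2% trimmed means of the deposited intensities were 200.08 for control and 200.07 for Cbs null, so both arrays had been brought to one scale and the values were used as deposited. Such scaling assumes that total signal is equal in both tissues, so every difference is relative to the rest of the array.

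Each array held 22690 probe sets, of which 64 were Affymetrix controls. Of the remaining 22626, the platform annotation gave 1 gene symbol for 20380, several for 691 and none for 1555. Gene identifiers of 20351 of the 1-symbol probe sets matched a mouse RefSeq gene table (assembly GRCm38.p6), which changed no symbol. That table served only for names and for the order of neighbouring genes, since no build is named with the array values. A gene was represented by its 1-symbol probe set with the highest mean log2 signal. Signals under 43.2, the 40th percentile of both arrays together, were raised to that floor, since weak signals on such arrays have no reliable order. A gene was called measured when it lay above the floor on at least 1 array. The log2 ratio was that of Cbs null over control, and a fold against a value below the floor is given as a lower bound ("at least").

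No statistical test was possible with 1 array per group. Genes were described by a fixed size rule of 2-fold. Measurement error within the arrays was estimated from pairs of probe sets of the same gene, with a technical SD of 0.24 where the weaker probe set was under 4 times the floor and 0.18 where both were brighter. The 18 hybridisation spike probe sets had log2 ratios from -0.29 to 0.09. The ratio of 3' to 5' signal was 1.31 in control and 1.25 in Cbs null for Gapdh, and 1.95 and 2.05 for Actb. The number of arrays limits the precision.

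Before the data were examined, 34 gene lists, the floor, the size rule, the rule for named genes and the alternative settings were fixed. Of 917 list genes written, 801 had a probe set of their own. The lists covered methionine and transsulfuration, ER stress, antioxidant, decidualization, uterine epithelium, progesterone and estrogen response, smooth muscle, contraction associated, uterine natural killer, macrophage and dendritic, neutrophil and lymphocyte genes. They also covered interferon response, endothelium, extracellular matrix, cell cycle, erythroid, trophoblast and embryo, Y-linked, adipocyte, ovary and steroidogenic, skeletal muscle, immediate early, coagulation and complement genes. The remaining lists were sterol and fatty acid synthesis, retinoid, imprinted, BMP, WNT and hedgehog, cytokine and chemokine, apoptosis, oxidative phosphorylation, ribosomal protein and reference genes. Some genes stand on more than 1 list, such as 6 of the 32 measured uterine epithelium genes, 8 of 25 decidualization genes and 6 of 20 estrogen response genes. A normal uterus expresses genes of most of these cell types.

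The median log2 ratio of each list with at least 5 measured members was given as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. A list in the outer 2.5% on either side was called higher or lower, which describes these 2 samples only. Of 29 lists with a median, 8 were called higher, 7 lower and 14 not apart, where 1.45 calls would be expected by chance if genes were independent.

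Named genes followed a rule. It took Cbs, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes above the floor on both arrays whose other measured probe sets went the same way, and the 4 largest lower bounds of fold in each direction among genes above the floor on 1 array. Genes known only by a clone, locus or predicted-gene name were passed over. It further took up to 4 members of each list that were at least 2-fold apart, or else its 2 members of highest signal, and any member of the methionine, reference and Y-linked lists. Genes named outside the rule are said to have been picked out after their values were seen, or are named as members of a list or of a test.

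The alternatives were centring on the median log2 ratio, quantile normalization, floors at the 20th and 60th percentiles, a pseudocount in place of the floor, the mean over a gene's probe sets, leaving out probe sets with the _s_at or _x_at suffix, thresholds of 1.5-fold and 3-fold, unmatched random lists and a list mean in place of the median. Leaving out members shared between lists was added after seeing the data. On data simulated from the control array with a noise SD of 0.2 on the log2 scale, 99.0% of 200 bright genes altered 3-fold were counted as 2-fold apart. That noise is below the technical SD of weak signals and leaves out variation between mice, so it checks the computation and not the rate of false counts. With real log2 ratios shuffled among genes of similar signal, 100% of lists of 25 genes shifted by 0.3 were called, and 3.5% of unshifted lists. The shuffling removes the shared regulation of list members and sets the rate for unshifted lists in advance. It therefore also checks the computation and not the rate of false calls for real lists. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.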

Results

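Gene expression was measured in mouse uterus on day 8 of pregnancy, in tissue taken between the implantation sites, where no embryo is attached. The mice were 4 months old and of a mixed C57Bl/6J and OLA129 background. A control sample and a sample from Cbs null females were each hybridised to 1 Affymetrix array, so there were 2 arrays in all. Cbs encodes cystathionine beta-synthase, which condenses homocysteine with serine in the first step of transsulfuration. The labels do not say whether a sample came from 1 animal or from a pool. The deposited signals had the same overall scale, with a median of 74.55 in the control sample and 75.6 in the Cbs null sample. The share of probe sets above the floor of 43.2 signal units was 60.1% in the control sample and 59.9% in the Cbs null sample. The floor was set as a percentile of both arrays together, so the mean of these shares was fixed in advance. Only the difference between the shares depends on the data, and neither share is a rate of detection.

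Cbs itself gave a weak signal in both samples. Its brighter probe set read 79.8 in the control sample and 42.6, just below the floor, in the Cbs null sample, at least 1.85-fold lower. A second Cbs probe set read 39.8 and 25.1, both below the floor. The direction matches the genotype labels, but the altered part of the gene is not given, so it is not known whether either probe set lies within it. With 1 array per group, no difference reported here has a replicate check, and no test or p-value is given.

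The comparison asked how the uterine wall between implantation sites differs in gene expression when Cbs is missing. Uterine epithelium genes were higher in the Cbs null sample as a group, among them the calcium-binding protein gene Calb1 (at least 7.73-fold) and the trypsin inhibitor gene Spink1 (5.04-fold). The mucin gene Muc5b, which is on no list, was 6.63-fold higher. The decidual prolactin family gene Prl8a2 (at least 9.82-fold) and the granzyme gene Gzmd (at least 8.75-fold) were lower, while most other decidualization and natural killer cell genes did not reach 2-fold. Members close to the floor in the control sample could not be counted as 2-fold lower. An example is Epas1 at 63.6, picked out after its value was seen. As groups, smooth muscle and extracellular matrix genes were modestly lower, macrophage and dendritic cell genes were modestly higher, and genes of methionine metabolism, the pathway in which Cbs acts, did not stand apart.

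Most genes differed little between the samples. Of 12393 genes with a probe set of their own, 8407 were above the floor on at least 1 array. Of these, 67 were at least 2-fold higher and 60 at least 2-fold lower in the Cbs null sample, together 1.51% of measured genes. At least 4-fold differences were found for 10 genes higher and 16 genes lower. Across the 7942 genes above the floor on both arrays, the median log2 ratio of Cbs null over control was 0.02 and its SD was 0.32. Independent probe sets of the same gene gave a technical SD of 0.22 for a log2 ratio, estimated over 2757 genes. That value covers measurement within these arrays and not the variation between mice. Of 18 genes at least 2-fold apart that had a second probe set above the floor, 17 went the same way in it and 7 were again at least 2-fold apart. The 2-fold counts depended on the floor, with 242 genes higher and 213 lower at the 20th percentile of signal and 30 higher and 31 lower at the 60th.

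**Figure D1:**
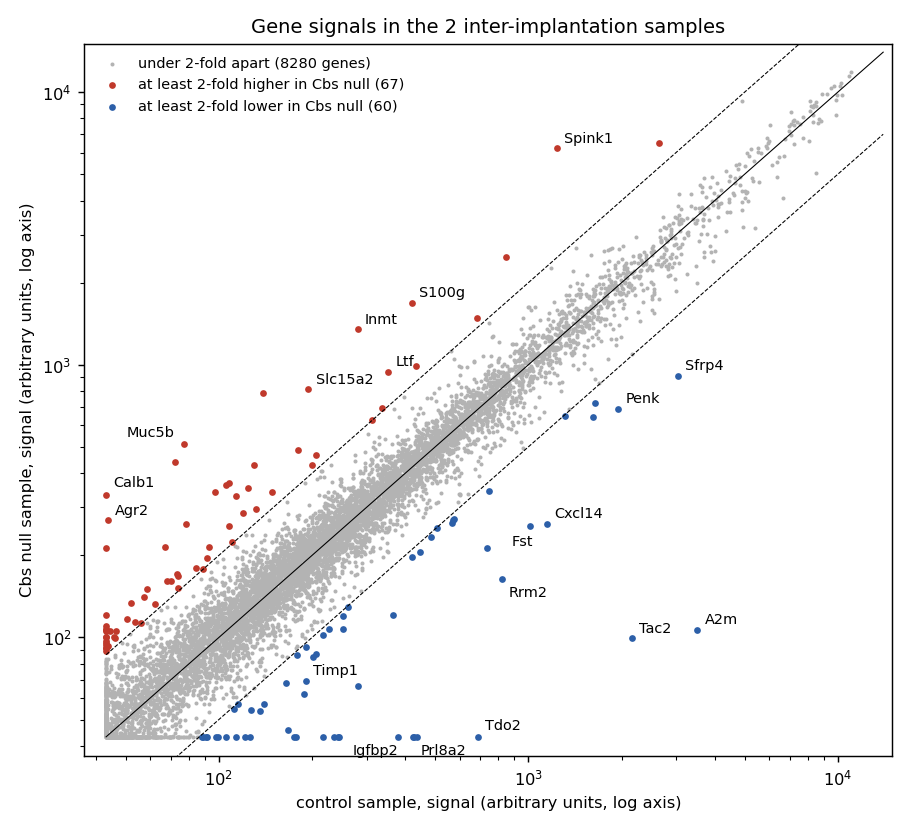
Signal of each measured gene in the control sample (x axis) and the Cbs null sample (y axis), in arbitrary units on log axes, with values below the floor of 43.2 drawn at the floor. The solid line marks equal signal and the dashed lines a 2-fold difference, and 67 genes lie at or above the upper line and 60 at or below the lower one.

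The gene furthest below the diagonal was A2m, the protease inhibitor alpha-2-macroglobulin, with a signal of 3510 in the control sample and 107 in the Cbs null sample, 32.8-fold lower. Tac2, which encodes the neurokinin B precursor, read 2160.2 and 99.5, 21.7-fold lower. Tdo2, the tryptophan-degrading dioxygenase, read 685 in the control sample and was below the floor in the Cbs null sample, at least 15.9-fold lower, and both of its probe sets behaved alike. The metallothionein gene Mt4 was at least 10.1-fold lower and the growth factor binding protein gene Igfbp2 at least 9.91-fold lower. Rrm2, a subunit of ribonucleotide reductase, read 819 and 164, a log2 ratio of -2.32, and a second probe set was 5.51-fold lower. The chemokine gene Cxcl14 was 4.38-fold and 5.13-fold lower in its pair of probe sets. The fibrillar collagen gene Col11a1 was 4.23-fold lower, the activin-binding protein gene Fst 3.95-fold lower and the secreted WNT antagonist gene Sfrp4 3.33-fold lower. Capn6, Hmgn5, Npy, Serpinb6b and the enkephalin precursor gene Penk completed the 12 lowest genes measured on both arrays, at 2.82-fold to 3.65-fold lower.

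Among the genes higher in the Cbs null sample, Muc5b, a gel-forming mucin, read 77.3 in the control sample and 513 in the Cbs null sample. Agr2, a disulfide isomerase of mucus-producing cells, was 6.16-fold higher, from a control signal of 43.7 that was barely above the floor. Wfdc18 was 6.11-fold higher and the methyltransferase gene Inmt 4.82-fold. Rpgrip1 was 5.68-fold higher in 1 probe set, with its other 3 below the floor on both arrays, and its log2 ratio of 2.51 was 0.63 when probe sets were averaged. Spink1 read 1234 and 6219. S100g, a calcium-binding protein of absorptive and uterine epithelium, read 419 and 1691, 4.03-fold higher. Ovgp1, the oviductal glycoprotein gene, was 3.43-fold higher, and Gpx2, an epithelial glutathione peroxidase, 3.32-fold higher. The clock-controlled transcription factor gene Dbp was 3.40-fold higher in its brighter probe set and 1.77-fold in the other. The peptide transporter gene Slc15a2 and Cuedc1 rested on 1 probe set each, at 4.17-fold and 3.51-fold, whereas their other probe sets gave 1.15-fold for Slc15a2 and 1.12-fold and 1.18-fold for Cuedc1. Of genes below the floor in the control sample, Calb1 read 334 in the Cbs null sample, the keratin gene Krt15 was at least 4.94-fold higher, the cell-surface mucin gene Muc1 at least 2.80-fold and the thyroid hormone carrier gene Ttr at least 2.55-fold.

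The uterine epithelium list had a median log2 ratio of 0.59, above all 10000 random gene lists matched on signal level. Of its 32 measured members, 30 were higher in the Cbs null sample, 8 of them at least 2-fold. With values raised to the floor, Calb1, Spink1, Ovgp1 and Muc1 differed most. Members below the floor in the control sample, Calb1, Muc1, Ttr, Cldn4 and Wnt7a, have only lower bounds, so their place in that order is uncertain. They counted as measured only through the Cbs null sample, so their direction was fixed in advance. The 2 members that were lower, Cdh16 at -0.69 and Aqp5 at -0.01, were picked out after their values were seen. So were Wfdc2 at 0.01, Aqp8 at 0.02 and Krt7 at 0.06, which count as higher but hardly differed. Keratin genes of stratified epithelium, likewise picked out, were also higher, Krt5 3.29-fold, Krt13 3.19-fold and Krt14 2.27-fold, beside Krt15, while Krt4, Krt6a, Krt6b, Krt16 and Krt17 were below the floor in both samples. The estrogen response list had a median of 0.25 (percentile 99.96), with 3 of 20 measured members at least 2-fold higher. These were Muc1, the lactoferrin gene Ltf (2.69-fold) and the small proline-rich protein gene Sprr2f (2.26-fold). With members that also stand on another list left out, its median was -0.01 and it no longer stood apart. The progesterone response list lay just inside the limit at 0.12 (percentile 97.1), 3 alternative settings called it higher, and Fst was its only member at least 2-fold apart.

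Smooth muscle genes were lower without exception, with all 25 measured members below 0 and a median log2 ratio of -0.41, under every matched random list. None reached 2-fold. Acta2 and Tpm2 stood at -0.07 and -0.18, whereas Actg2 and Des, picked out after their values were seen, stood at -0.77 and -0.68. The extracellular matrix list had a median of -0.42, also under every matched list, with 27 of 36 members lower. At least 2-fold lower were the metalloproteinase inhibitor gene Timp1 (2.76-fold), the elastin gene Eln (2.13-fold) and the matrilysin gene Mmp7 (2.13-fold). The adipocyte list was lower at -0.32 (percentile 0.01), with 12 of 13 members below 0 and Car3 and Fabp4 at -0.16 and -0.37. The sterol and fatty acid synthesis list was lower at -0.20 (percentile 0.03), with Elovl6, a fatty acid elongase, 2.08-fold lower. Of 3 measured skeletal muscle genes, Tnni2 and Acta1 were 2.12-fold and 2.03-fold lower, too few members for a list median.

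**Figure D2:**
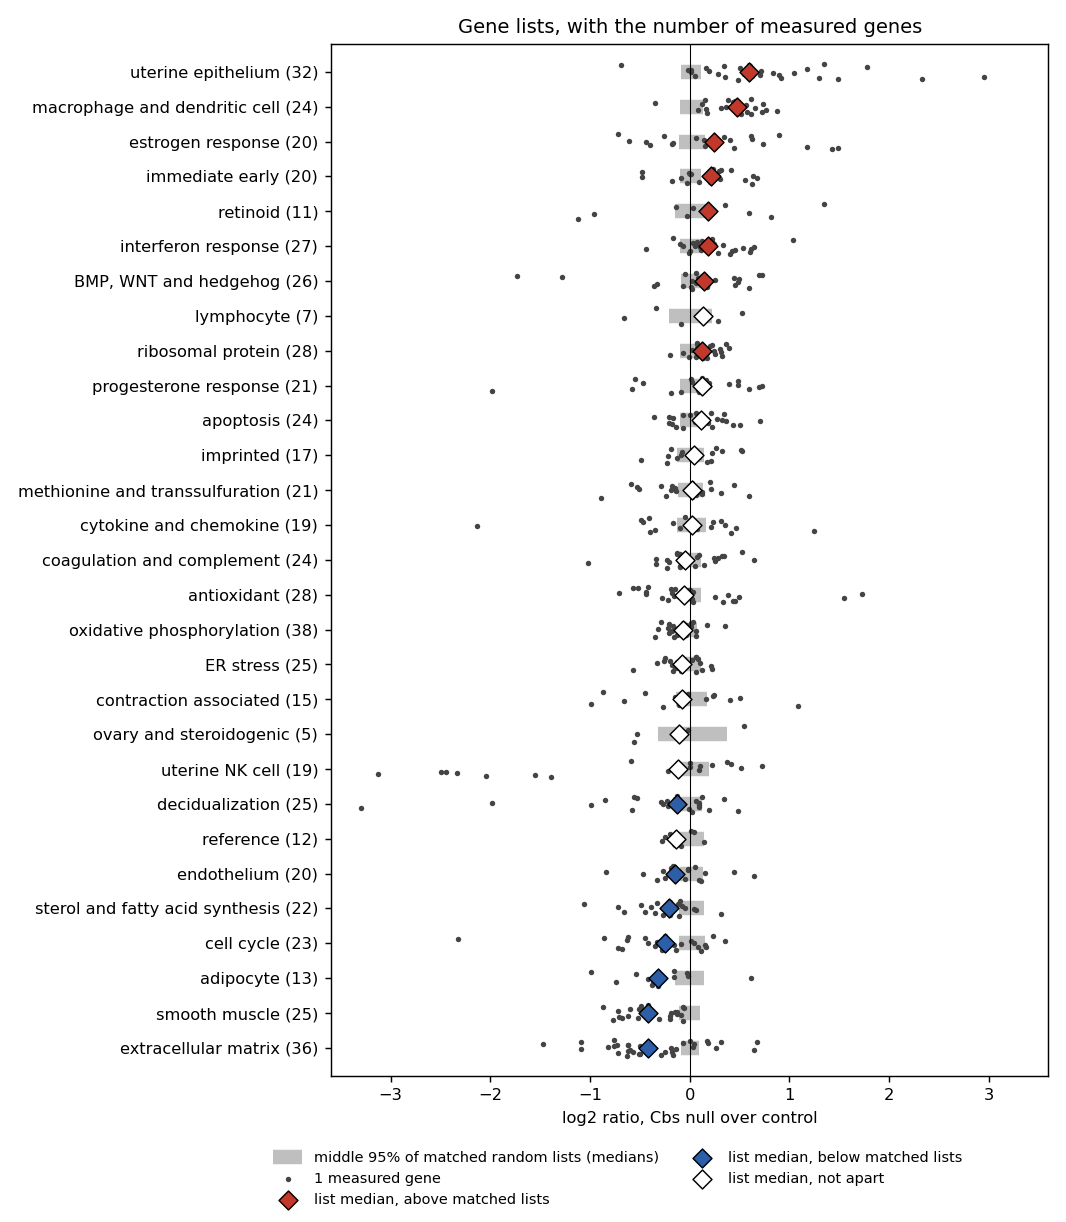
Log2 ratio of Cbs null over control (x axis) for the measured members of each gene list with at least 5 of them (dark dots) and their median (diamonds), beside the middle 95% of medians of 10000 random lists matched on signal level (grey bars). Uterine epithelium (0.59) and macrophage and dendritic cell (0.47) lie furthest above the random lists, and extracellular matrix (-0.42) and smooth muscle (-0.41) furthest below.

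Among the decidualization genes, Prl8a2 read 424 in the control sample and 5.8 in the Cbs null sample, and Fst 1012 and 256. Of the other 23 of 25 measured members none reached 2-fold against the floor, but Ptgs2, picked out after its value was seen, was below it in the Cbs null sample and so at least 1.99-fold lower. The list median of -0.12 was low among matched lists (percentile 0.97). That call was lost when probe sets of a gene were averaged, at -0.081. The 7 granzyme genes Gzma to Gzmg were the uterine natural killer cell genes at least 2-fold lower, of 19 measured. Gzmd was at least 8.75-fold lower, Gzmg 5.63-fold, Gzmf 5.46-fold and Gzme 5.03-fold, all measured against the floor. Gzmd, Gzme, Gzmf and Gzmg are close copies of each other, so their probe sets may share targets and their single values are uncertain. The other members lay between -0.59 for Srgn and 0.73 for Klra8, both picked out after their values were seen. The median of the whole list, -0.11 (percentile 5.09), was not apart from matched lists, although it was called lower under 5 alternative settings.

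Some lists of other cell types, and the interferon response and immediate early lists, also stood apart. The macrophage and dendritic cell list had a median of 0.47, above all matched lists, and 23 of 24 measured members were higher, with the antigen presentation genes H2-Aa and Cd74 at 0.46 and 0.49. The interferon response list was higher at 0.19 (percentile 99.75), led by the immunoproteasome subunit gene Psmb9 at 2.05-fold. The immediate early list, fixed as a check of sample quality and not as a cell type, was higher at 0.22 (percentile 99.98), with Nfkbia at 0.23 and Egr1 at 0.09. Of its 20 measured members, 14 were higher. A difference in quality between the samples is therefore not excluded, and its bearing on the other lists was not tested. The endothelium list was lower at -0.14 (percentile 0.34), with Ramp2 at 0.05 and Esam at 0.15 going the other way, and its call was lost with a mean in place of the median (-0.085). The lymphocyte list, 7 measured genes, was not apart at 0.13 but was called lower at -0.29 with the floor at the 20th percentile, with Jchain at -0.66 and Cd52 at 0.53. Of 3 measured neutrophil genes, Ltf was 2.69-fold higher, and of 3 measured erythroid genes, Car2 and Hbb-b2 stood at -0.51 and -0.20 and Alas2, picked out after its value was seen, at 0.72. No member of the trophoblast and embryo list (24 on the array) or of the Y-linked list (5 on the array) was above the floor in either sample.

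Cell cycle genes were lower as a list at -0.24, below every matched list, but only Rrm2 differed at least 2-fold, and with the floor at the 60th percentile the median was -0.14 and the call was lost. Ribosomal protein genes were slightly higher at 0.13 (percentile 99.76), a call lost after quantile normalization (0.062). The BMP, WNT and hedgehog list was higher at 0.14 (percentile 98.7), a call that 3 alternative settings ended, although its members at least 2-fold apart, Sfrp4 and Sfrp1 (2.42-fold), were lower. The retinoid list was just called higher at 0.19 (percentile 97.8), with Ttr higher and the retinol carrier gene Rbp4 2.17-fold lower, and 6 alternative settings ended that call.

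In the methionine and transsulfuration list, no member of 21 measured differed 2-fold, and the median was 0.02 (percentile 55.6). With probe sets of a gene averaged, that median was -0.091 and the list was called lower. Cth, which acts directly after Cbs, read 121 and 122, and Ahcy, which forms homocysteine, read 579 and 490. Mtrr, which reactivates methionine synthase, was 1.51-fold higher, and the sulfur oxidation genes Suox and Sqor stood at -0.59 and -0.53. The ER stress list did not stand apart at -0.07 (percentile 5.7), with Hspa5 at 0.06 and Xbp1 at 0.12. The antioxidant list did not either at -0.05, apart from a call of lower at -0.094 with the floor at the 60th percentile, although Gpx2 (3.32-fold) and the glutathione transferase gene Gsta4 (2.92-fold) were higher. Also not apart were contraction associated (-0.07, but called higher at 0.16 with the floor at the 60th percentile, with Gjb2 at least 2.12-fold higher), coagulation and complement (-0.05, Tfpi2 2.02-fold lower) and cytokine and chemokine genes (0.02). In that last list Cxcl14 was lower and Ccl8 was 2.37-fold higher. The same held for ovary and steroidogenic (-0.11, Scarb1 at 0.55), imprinted (0.04, Dcn at 0.26), apoptosis (0.11, Mcl1 at 0.19) and oxidative phosphorylation genes (-0.06, Cox6b1 at -0.06). The 12 reference genes had a median of -0.13 (percentile 3.01), called lower under 2 alternative settings, from Gusb at -0.28 to Ywhaz at 0.15.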

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

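The tests in this part were chosen after the results were seen, except the stratified epithelium test, which was written before the genes it measures were looked at.

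Signal outside the gene-level comparison drew attention to probe sets that carry no gene symbol or several, of which 9 were at least 2-fold higher and 12 at least 2-fold lower in the Cbs null sample. A probe set shared by the alpha-globin genes Hba-a1 and Hba-a2 read 505.5 in the control sample and 1179 in the Cbs null sample. A probe set shared by Gzme and Gzmd read 456 and 0.6. No explanation was tested for these probe sets.

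The first pattern was the near loss of Prl8a2, Tdo2 and granzyme signals in the Cbs null sample. No sign of conceptus tissue was seen in the control piece. Of 24 trophoblast and embryo genes, 0 were above the floor there, the highest being Hand1 at 24.0 signal units. The list members Prl3d1, Prl3b1 and Prl2c2 had no probe set of their own, so trophoblast that expresses mainly these genes is not excluded. Fewer natural killer cells of every kind could not be decided, since too few genes outside the granzymes were bright enough. Klrd1, Klra8 and Ctsw were, with a median log2 ratio of 0.23. Brightness was the mean over both arrays, so members that fell passed less easily and that median is not evidence against a fall. Srgn, left out of that median because many leukocytes make it, stood at -0.59. Decidual cells carried over from implantation sites into the control piece and a weaker decidual reaction between sites cannot be told apart, as both predict a lower decidualization list (-0.12). A weaker decidual reaction in Cbs null females remains a possible explanation that the 2 samples cannot separate from dissection.

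The second pattern was higher epithelial genes beside lower smooth muscle genes. A smaller share of smooth muscle cells alone would lift other cell types alike. The epithelium median, however, exceeded the endothelium median by 0.74 (bootstrap interval over members 0.52 to 0.93). The macrophage median exceeded it by 0.62 (0.40 to 0.73). These values argue against that narrow form only, and the intervals leave out variation between mice. A smaller muscle layer together with its vessels, matrix and fat stays open. The endothelium (-0.14), extracellular matrix (-0.42) and adipocyte (-0.32) lists were lower too. One larger share of epithelial cells alone would raise all members by 1 factor. The rule took 3 or more members beyond 3 technical SDs from the list median as a result against it. Of 26 bright members, 8 lay beyond that limit with the SD of their own signal level, where measurement error alone predicts 0.22. With the SD of weak signals, 2 of 26 did, and the SD of members was 0.54. The 8 members argue against that narrow form only, 1 factor with nothing but measurement error. A larger share of epithelial cells with variation between mice added could not be decided, since 1 array per group does not measure that variation. Stratified epithelium of the lower genital tract in the Cbs null piece stayed open too. Of 31 members on the array not seen beforehand, 13 were measured. Their median was 0.23 (percentile 97.4), between the values predicted with and without it. The others, among them Krt4, Krt6a and Trp63, were below the floor in both samples. Sprr1a, Ly6d and Lgals7 were measured only through the Cbs null sample and Dmkn only through the control sample, which fixed their directions. The test also did not separate stratified epithelium from the rise of the uterine epithelium list (0.59). The 6 members that prompted the test, Krt5, Krt13, Krt14, Krt15, Pkp1 and Calml3, were all at least 2.22-fold higher. An effect of the genotype on epithelial expression is likewise open and was not tested separately, since dissection, tissue make-up and genotype coincide in 1 pair of samples.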

How the results depend on the processing

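Leaving out members shared between lists was the only alternative in this part chosen after seeing the data. Of 15 called gene lists, 8 kept their call under every alternative: uterine epithelium, macrophage and dendritic cell, interferon response, immediate early, smooth muscle, extracellular matrix, adipocyte, and sterol and fatty acid synthesis. Counts of genes at least 2-fold higher and lower were 242 and 213 with the floor at the 20th percentile, 30 and 31 at the 60th, and 35 and 33 with a pseudocount. All 67 higher and 60 lower genes were among those counted at the 20th percentile, which was fixed in advance, since a lower floor cannot shrink a fold. A 1.5-fold threshold gave 302 and 284, and a 3-fold threshold 16 and 22. Scaling mattered less, with 63 and 65 after centring and 65 and 63 after quantile normalization. The list medians that crossed a calling limit follow by setting. With the floor at the 60th percentile they were antioxidant -0.094, contraction 0.16 (turned above 0) and natural killer cell -0.59, now called, and cell cycle -0.14, retinoid 0.033 and BMP, WNT and hedgehog 0.12, no longer called. With the floor at the 20th percentile, progesterone 0.14, lymphocyte -0.29 and reference genes -0.13 became called, the lymphocyte median thereby turning below 0. With a mean over probe sets, methionine -0.091 (also below 0) and natural killer cell -0.11 became called, and decidualization -0.081, endothelium -0.080 and retinoid 0.033 lost their calls. Quantile normalization called progesterone 0.13 and reference -0.15 and not ribosomal protein 0.062, and a pseudocount called progesterone 0.12. Without _s_at and _x_at probe sets, natural killer cell -0.17 became called and retinoid 0.11 lost its call. A list mean called natural killer cell -0.73 and not endothelium -0.085, retinoid 0.12 or BMP, WNT and hedgehog 0.063, and unmatched random lists did not call retinoid 0.19. With shared members left out, estrogen response reversed to -0.010, retinoid 0.033 and BMP, WNT and hedgehog 0.087 lost their calls, and natural killer cell -0.17 became called. The ovary list had no value with the floor at the 60th percentile or with shared members left out, because too few members remained. For the other crossings the cause was not tested. Of 51 named genes at least 2-fold apart, 28 stayed so in every alternative that measured them. Genes such as Muc1, Ttr, Gjb2 and Tfpi2 lie so close to the floor that their folds vanished under the higher one. No leave-one-out analysis, paired analysis or other split was possible with 1 array per group. Weak signals limit the granzyme and Prl8a2 folds to lower bounds.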

Other observations

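The tests in this part were written before the genes they measure were looked at, but the time-of-day test was prompted by Dbp and Cirbp, whose values had been seen, and the bootstrap interval and the Poisson limit were added after the results were seen.

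Circadian clock genes had no list of their own at the start, although Per1 stood on the progesterone response list, and were picked out after Dbp was seen. Nr1d2, a nuclear receptor that represses Arntl, read 561 in the control sample and 1119 in the Cbs null sample, 1.99-fold higher. Per3 was 1.94-fold higher, Nr1d1 1.60-fold, Hlf 1.52-fold and Tef 1.46-fold. In the opposite arm, Cry1, Nfil3 and Arntl stood at log2 ratios of -0.49, -0.40 and -0.24, and Clock and Npas2 at -0.06 and 0.02. Usp2 and Per2 rose less, at 0.44 and 0.22. Per1 (0.01) and Bhlhe40 (-0.08) did not share the direction of Dbp.

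Some stratified epithelium genes, picked out after their values were seen, differed between the samples in both directions. Beside the keratin genes already given, Calml3 was at least 2.46-fold higher and Pkp1 at least 2.22-fold higher. The desmosomal genes Dsp and Perp were 1.92-fold and 1.84-fold higher, whereas Dmkn was at least 2.05-fold lower, Jup 1.61-fold and Cdh3 1.58-fold.

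A hypothesis for the clock genes is a different time of day at dissection. The 8 measured genes in phase with Dbp, leaving out Dbp, Cirbp and Per1, had a median log2 ratio of 0.57 and the 5 genes of the opposite arm -0.24. The difference of 0.81 (bootstrap interval over members 0.38 to 1.22) lay above the 0.1 or less predicted without a shift in phase. It also met the size set beforehand for such a shift, but the lower end of the interval did not. The interval treats the genes as independent and leaves out variation between mice. The values are consistent with samples taken at different times of day, but a clock altered by the genotype would give the same values, and times of dissection are not given in the sources used here.

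A further hypothesis was that alleles from the strain that carried the null mutation, linked to Cbs on chromosome 17, account for differences near the gene. Of the 50 measured genes nearest to Cbs, 25 on each side, 2 were at least 1.5-fold apart, Pi16 at -0.82 and Pde9a at 0.60. Random runs of 50 neighbouring genes on other chromosomes had a median of 3, and the middle 95% of them reached up to 8, above the exact Poisson upper limit of 7.22 for a count of 2. The test gave no sign of a cluster of differing genes around Cbs.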
